A study of Mus musculus with 2 samples.

How the data were processed

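MicroRNA sequencing libraries of total RNA from the gastrocnemius of female B6CASTF1/J mice aged 25 days were analysed, with a size range below 30 given in the labels. Per the labels, the libraries were biological replicates 1 and 2 of 1 group, from females numbered separately but with the same donor identifier. The authors deposited 1 table of raw counts per library, without a header, with 3 count columns per microRNA gene. From the values, these hold reads on either strand, on the strand of the gene and on the opposite strand, and 4 rows at the top tally reads given to no gene. Per the labels the assembly was mm10, and the annotation was GENCODE M21 per the readme files deposited with the libraries. The aligner, the counting tool and their filters are not given in the sources used here. All 2202 gene identifiers matched microRNA genes of GENCODE M21, from which symbols, positions, host genes and hairpin sequences were taken.

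The strand-specific column with the larger total, which was the sense column in both libraries, was the measure used throughout. Replicate 1 held 7367359 reads in all and replicate 2 held 24096793. Reads that aligned to several places made up 69.1% ± 0.794 (SD, n = 2) of these, unaligned reads 7.02% ± 1.32 and reads outside annotated microRNA genes 1.92% ± 0.305; these rows stayed out of library totals. CPM were sense counts on microRNA genes scaled to a library total of 1000000. In the either-strand column, 356588 reads of replicate 1 and 1318706 of replicate 2 were tallied as ambiguous, and 64 microRNA genes overlap another on the opposite strand.

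A gene was called detected at a CPM of at least 2 in both libraries. Shares of counts were given with exact (Clopper-Pearson) 95% intervals. Log2 ratios in list summaries used a pseudocount of 1 CPM, and ratios of single genes an offset of 0.5 counts. Genes with a summed count of at least 10 were compared between the libraries with a two-sided exact binomial test, with library totals as the odds and Benjamini-Hochberg adjustment at 0.05. List medians were placed among 10000 random lists, drawn for levels from genes detected in at least 1 library and for ratios within 10 bins of mean expression. The common biological coefficient of variation was estimated with edgeR 4.0.16 and TMM scaling, and DESeq2 1.42.0 gave alternative size factors, both in R 4.3.3. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

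The exact binomial test was tested on simulated counts without biological variation, of which 363 genes reached the minimum of 10 counts. Whether or not they reached it, it recovered 66.0% of 100 genes changed 1.5-fold and 87.0% of 100 changed 3-fold, and called 2.35% of the 170 unchanged genes that reached it. In simulated libraries of 324 genes the estimated coefficient of variation was 10.3%, 29.7% and 61.0% for true values of 10, 30 and 60%.

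Before the data were examined, 20 gene lists with 236 entries were fixed: striated muscle, slow fibre, erythroid, immune, endothelial, smooth muscle and fibroblast, neural, epithelial, liver with gut and pancreas, and adipose markers, and 10 lists of families, clusters and multi-copy genes. Also fixed were 21 pairs of a multi-copy gene and a cluster partner, of which 20 had a detected member. Genes were named by a rule fixed then: the 20 most abundant, list and pair members, and the 5 largest log2 ratios in each direction among genes past the test with a mean CPM of at least 10. Alternatives were other CPM minimums, the either-strand column, all aligned reads as denominator, other pseudocounts, TMM and DESeq2 scaling, no filter, and each replicate left out. With 2 libraries of 1 group, no test between conditions was possible.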

Results

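MicroRNA abundance was measured by small RNA sequencing in the gastrocnemius, a large muscle of the calf, of 25-day-old female mice of the strain B6CASTF1/J, the F1 cross of C57BL/6J and CAST/EiJ. The 2 libraries formed 1 group of 2 biological replicates, per the labels. The labels number the source females separately but give both libraries the same donor identifier, so SDs and the coefficient of variation measure the spread between these 2 libraries, whether or not it is between animals. No treatment or second tissue was included, so the design implied a description of the microRNA pool and a comparison of the libraries with each other. Replicate 1 held 1573213 counts on the strand of annotated microRNA genes and replicate 2 held 5429127, a ratio of 3.45. Levels are given as CPM, counts scaled to a library total of 1000000. A count of 0, which allows up to 3 counts, set an upper limit of 1.91 CPM in replicate 1 and 0.553 CPM in replicate 2. Of 2202 annotated microRNA genes, 520 had at least 1 count in replicate 1 and 614 in replicate 2, and 324 reached a CPM of 2 in both. No information on molecular identifiers was used, so all intervals, floors and exact binomial tests cover counting error only. Counts belong to whole hairpins, and the arms of a hairpin were not distinguished.

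Counts assigned to microRNA genes were dominated by few genes. The 10 most abundant genes held 62.1% ± 0.478 (SD, n = 2) of all microRNA-gene counts, and the 20 most abundant held 79.8% ± 0.713. Reads aligned to several places, 69.1% of all reads, were assigned to no gene, so this ranking can miss genes with copies elsewhere. As a share of all aligned reads, the 10 genes held 14.7%. Mir378a, which lies in an intron of Ppargc1b, a coactivator gene of mitochondrial metabolism, had a mean of 98707 CPM ± 6479 (SD, n = 2), and Mir126a, within Egfl7 and typical of endothelium, 98348 ± 7099 CPM. These means differed by less than the spread between replicates, and the highest gene was Mir143 in replicate 1 and Mir126a in replicate 2. Mir143, a microRNA of smooth muscle and fibroblasts, averaged 93431 CPM with an SD of 48308, because replicate 1 had 127590 CPM and replicate 2 had 59272. Mir206, a microRNA specific to skeletal muscle, averaged 53673 ± 26600 CPM, with 34864 CPM in replicate 1 and 72482 in replicate 2. Mir23a, at 55454 ± 4874 CPM, and Mir22, at 53408 ± 6044 CPM, differed less between the libraries. Further genes among the 20 were Mirlet7g, Mir23b, Mirlet7i, Mir26b, Mir99a, Mir127, Mir411, Mirlet7b, Mir322, Mirlet7d, Mir30a, Mir30e, Mir335 and Mir10b, the last at 10502 ± 25.3 CPM.

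**Figure D1:**
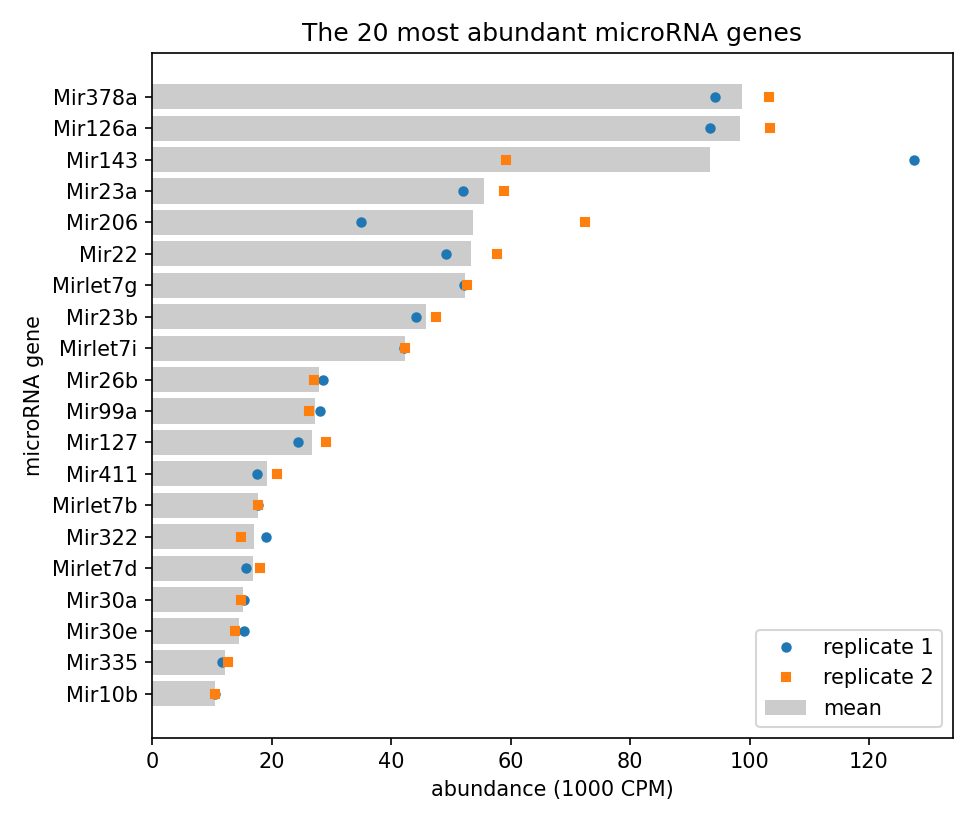
Abundance of the 20 microRNA genes with the highest mean, in units of 1000 CPM. Grey bars show the mean of 2 libraries, circles replicate 1 and squares replicate 2; Mir143 and Mir206 show the widest gaps, with 127590 and 59272 CPM for Mir143.

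In the mm10 assembly, the hairpin of Mir378a (ENSMUSG00000105200.1) spans chromosome 18 from 61397835 to 61397900 on the reverse strand. Mir126a (ENSMUSG00000065540.1) spans chromosome 2 from 26591357 to 26591429 and overlaps an annotated exon of Egfl7 on the same strand. Mir143 (ENSMUSG00000065445.3) lies between genes on chromosome 18, from 61649196 to 61649258. Mir206 (ENSMUSG00000065559.1) lies on chromosome 1 from 20679010 to 20679082, within an exon of the long non-coding RNA gene Gm28653. Mir378a, Mir126a and Mir30e each lie opposite another annotated microRNA gene, Gm25301, Mir126b and Mir30f. When strand was ignored, Mir378a and Mir30e were listed at 0 CPM and Mir126a at 2.33 CPM, so their levels rest on the strand-specific counts.

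Genes of striated muscle held a modest share of the counts, and nearly all of it came from Mir206. The list of 12 such genes held 5.57% ± 2.73 (SD, n = 2) of the counts. It held 3.64% of replicate 1 (exact binomial 95% interval 3.61 to 3.67) and 7.50% of replicate 2 (7.48 to 7.52). Without Mir206 the share was 0.204%, an alternative chosen after the data were examined. The next members were Mir486, in the ankyrin gene Ank1, at 684 ± 46.7 CPM, Mir208b, in the slow myosin gene Myh7, at 607 ± 548 CPM, and Mir1a-2 at 348 ± 42.5 CPM. Mir499, in Myh7b, had 302 ± 161 CPM, and Mir133b had 27.4 ± 0.761 CPM. The median of the 11 list members detected in at least 1 library was 27.4 CPM, at percentile 20.0 of 10000 random lists of detected genes, or 33.7 with the either-strand column and 13.3 without replicate 1. Mir1a-1, Mir1a-2, Mir1b, Mir133a-1 and Mir133a-2 share a stretch of 22 bases with a microRNA gene elsewhere and are uncertain for the reason measured below. Mir486 and Mir3107 overlap on opposite strands, as do Mir1a-2 and Mir1b, so their levels rest on the strand-specific counts.

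Markers of other cell types were present at very different levels. The endothelial list, made up almost wholly of Mir126a, held 9.83% ± 0.710 of the counts. The smooth muscle and fibroblast list held 9.82% ± 4.92, with Mir143, Mir145a at 2623 ± 1282 CPM and Mir214 at 2014 ± 481 CPM leading. The immune list held 0.330% ± 0.0318, led by Mir155 at 835 ± 66.2 CPM and Mir142, a marker of blood cells, at 587 ± 356 CPM. The erythroid list held 0.164% ± 0.150, from Mir451a at 1302 ± 1173 CPM and Mir144 at 343 ± 323 CPM. The neural list held 0.127% ± 0.0646, most of it from Mir338, a microRNA of myelinating glia, at 1165 ± 588 CPM. Neither Mir124a-1, Mir124a-2 nor Mir124a-3, typical of neurons, had a count in either library; these loci share their mature microRNA, so reads that align to several of them would not be counted. The epithelial list held 0.0387% ± 0.0186, led by Mir203 at 289 ± 101 CPM.

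Several conserved families and clusters were abundant. The let-7 family held 14.0% ± 0.201 of the counts, with Mirlet7g at 52398 ± 395 CPM, Mirlet7i at 42234 ± 221 CPM and Mirlet7b at 17666 ± 22.4 CPM. The miR-23, miR-27 and miR-24 clusters held 11% ± 0.75, mostly from Mir23a and Mir23b. The miR-10, miR-99, miR-100 and miR-125 families held 5.52% ± 0.128, and the miR-30 family 3.75% ± 0.197. Multi-copy members of these lists, such as Mirlet7a-1, Mirlet7c-1, Mir24-1, Mir30c-1 and Mir125b-1, have uncertain levels for the reason measured below. These family shares therefore rest mostly on single-copy members. The imprinted Dlk1-Dio3 cluster on chromosome 12 held 8.74% ± 0.95, and 41 of its 42 listed genes were detected in both libraries. Mir127, at 26718 ± 3234 CPM, and Mir411, at 19135 ± 2361 CPM, were its most abundant members. The medians of the let-7 and Dlk1-Dio3 lists lay at percentiles 99.99 and 99.73 of random lists of detected genes.

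The replicates ranked genes alike, with differences in level at part of them. Across the 324 detected genes, which are not independent replicates, Spearman's rho was 0.986 and Pearson's r on log2(CPM + 1) was 0.989. The common biological coefficient of variation between the libraries, estimated with edgeR from 1 residual degree of freedom, was 24.6%, which corresponds to an SD of 0.50 for the log2 ratio of a single gene. Of 364 genes with a summed count of at least 10, 164 differed at an adjusted p under 0.05 in a two-sided exact binomial test, 109 higher in replicate 1 and 55 higher in replicate 2. This test holds reads as the only source of error, and 59 of the former and 13 of the latter had log2 ratios beyond that SD. The SD came from the same 2 libraries, so part of the genes is bound to lie beyond it. At least 2-fold differences were seen in 34 of the genes higher in replicate 1 and 3 of those higher in replicate 2. The split depended on scaling: with DESeq2 size factors 172 genes differed, 78 higher in replicate 1 and 94 higher in replicate 2. The median log2 ratio of replicate 2 over replicate 1 across detected genes was -0.13, and DESeq2 scaling moved all ratios by 0.13. A chi-square statistic of 134418 on 363 degrees of freedom showed that these were not 1 library deposited repeatedly. These tests compare 2 libraries of 1 group and not conditions.

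**Figure D2:**
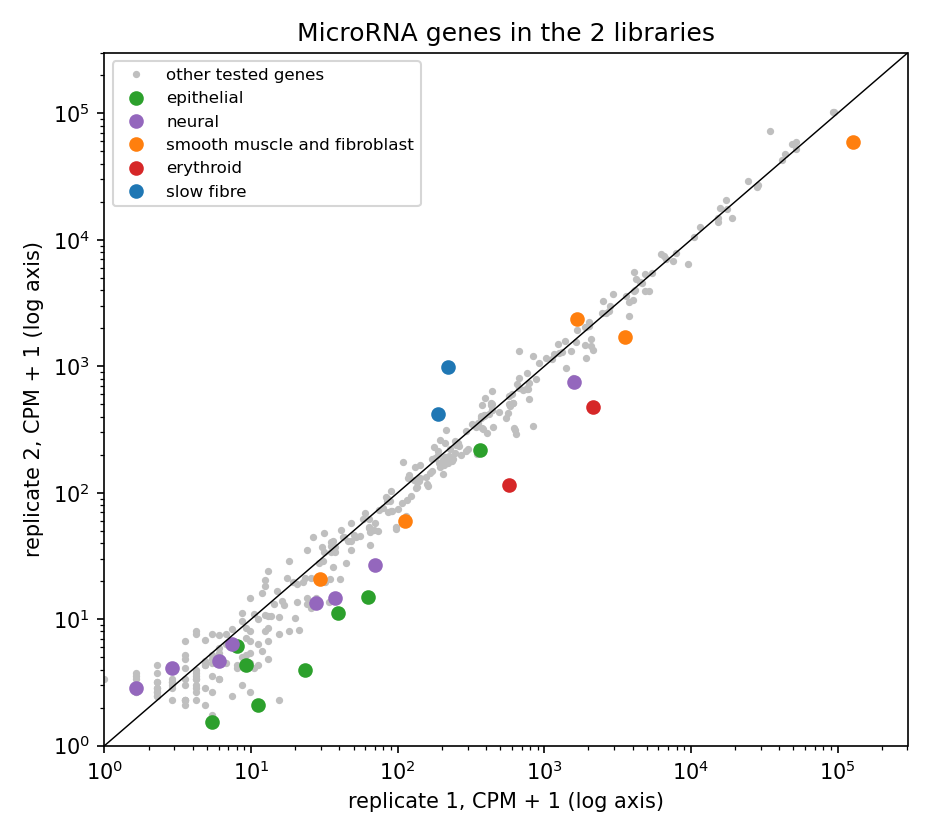
CPM + 1 of the 364 tested microRNA genes in replicate 1 and replicate 2, on log axes, with the line of equal values. Coloured points mark 5 of the 20 lists, whose members were fixed beforehand. Among the 5 are the 4 lists picked because they moved, and genes only in other lists are grey. Mir451a and Mir144 of the erythroid list lie below the line, at 2131 and 571 CPM in replicate 1 against 473 and 114 CPM in replicate 2.

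Genes of slow muscle fibres were higher in replicate 2. Mir208b had 219 CPM in replicate 1 and 994 CPM in replicate 2, 4.53-fold higher (log2 ratio 2.18, exact 95% interval 2.02 to 2.34). Mir499 was 2.21-fold higher (log2 ratio 1.14, 0.97 to 1.32), and both passed the exact binomial test. Mir206 was 2.08-fold higher in replicate 2, Mir381 of the Dlk1-Dio3 cluster 1.97-fold and Mir133a-1 1.89-fold. Mir133a-1 rested on 19 and 124 counts, with a log2 interval of 0.22 to 1.70. Of the 11 muscle genes tested, 5 were higher in replicate 2 and 3 in replicate 1, with 3 not past the test, and 8 also passed when adjusted over the list alone. The 3 higher in replicate 1 were Mir1a-2, Mir208a and Mir133a-2, the last on 12 and 11 counts. Mir133a-1 and Mir133a-2, which share their mature microRNA, thus went opposite ways at low counts. The median log2 ratio of the muscle list was 0.17, at percentile 98.2 of 10000 random lists matched on expression. This median was the ratio of Mir1a-1 alone, on 22 and 86 counts, and the middle 95% of random lists reached 0.15. Mir1a-1 is a multi-copy gene with an uncertain level. These comparisons had no replicate check beyond the 2 libraries.

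Listed genes of red blood cells and epithelium, and part of those of nerve and of smooth muscle and fibroblasts, were higher in replicate 1. Mir451a was 4.51-fold and Mir144 5.00-fold higher there; both erythroid genes tested passed, over all genes and adjusted over the list alone. Of 8 epithelial genes tested, 6 were higher in replicate 1 and none in replicate 2, or 7 past the test adjusted over the list alone. Mir183 was 7.55-fold, Mir182 4.40-fold and Mir200c 3.76-fold higher in replicate 1, although Mir183 rested on 35 and 16 counts. Of 8 neural genes, 4 were higher in replicate 1, the same number adjusted over the list alone, with Mir338 at 1581 and 749 CPM. Of 5 smooth muscle and fibroblast genes, 3 were higher in replicate 1 and Mir214 in replicate 2, or 5 past the test adjusted over the list alone. Median log2 ratios of replicate 2 over replicate 1 were -1.46 for the epithelial, -1.07 for the neural and -0.90 for the smooth muscle and fibroblast list. These medians lay at percentiles 0.015, 0.35 and 0.35 of matched random lists.

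The immune list went both ways. Of 6 immune genes, 3 were higher in replicate 1, among them Mir142 at 839 and 336 CPM, and 2, Mir146 and Mir342, were higher in replicate 2; 5 passed adjusted over the list alone. The median log2 ratio of the immune list was -0.07 with library totals and 0.05 with DESeq2 size factors, at percentile 47.3 with totals. Mir126a, the single endothelial gene tested, had a log2 ratio of 0.15, past the exact binomial test but within the SD of 0.50 for a single gene.

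Most tested genes of the proliferation-linked miR-17 clusters were also higher in replicate 1, and part of the Dlk1-Dio3 cluster was higher in replicate 2. Of 12 genes of the miR-17, miR-106a and miR-106b clusters tested, 8 were higher in replicate 1 and none in replicate 2, 8 also adjusted over the list alone. Mir106b had 1565 CPM in replicate 1 and 800 CPM in replicate 2, and the list median was -0.73, at percentile 0.21. In the Dlk1-Dio3 cluster 19 of 41 genes were higher in replicate 2 and 2 in replicate 1, 21 adjusted over the list alone, and the median was 0.14, above every random list drawn. The let-7 median was -0.01 with library totals and 0.07 with TMM scaling, with 3 genes higher in replicate 2 and 4 in replicate 1, 7 adjusted over the list alone. In all, 6 of 15 lists with at least 3 detected genes lay outside the middle 95% of random lists. The muscle list did so by a median that rested on Mir1a-1 alone, at low counts. Random lists draw genes singly, whereas genes of the same cluster are not independent. Percentiles of lists with clustered genes, here and above, can thus look more extreme than they are.

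**Figure D3:**
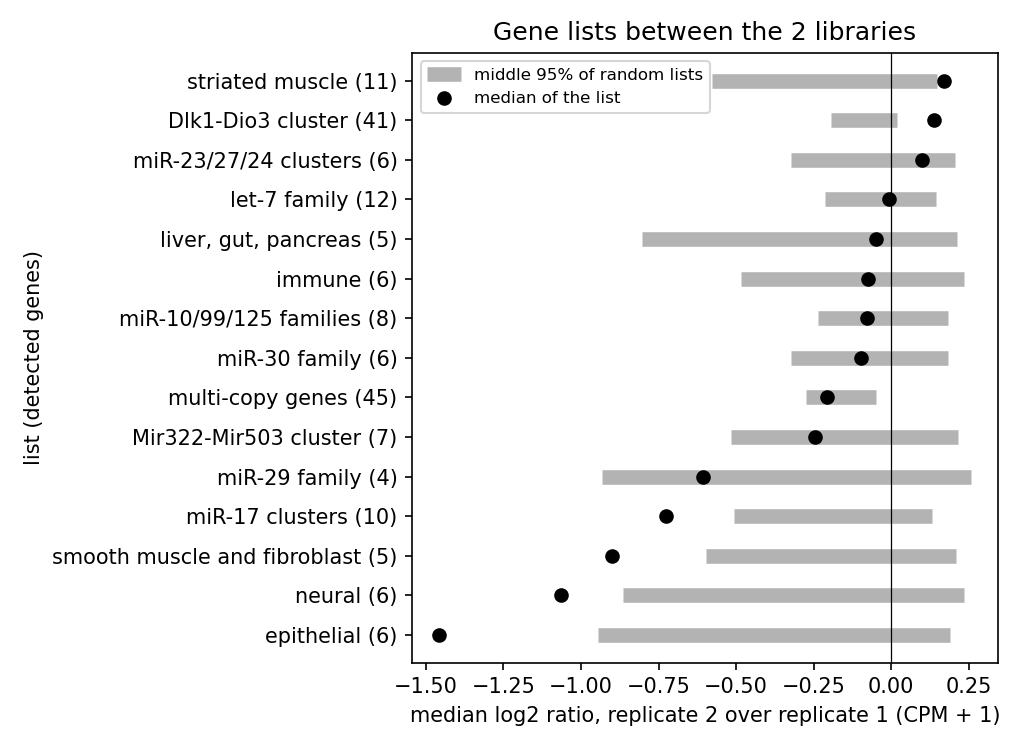
Median log2 ratio of CPM + 1, replicate 2 over replicate 1, for 15 gene lists (black points), with the middle 95% of 10000 random lists matched on expression (grey bars). Numbers in parentheses are detected genes; the epithelial median of -1.46 is the lowest.

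Genes whose mature microRNA is encoded at more than 1 locus were mostly counted below single-copy genes of the same cluster. Reads that aligned to several places made up 68.6% of all reads in replicate 1 and 69.7% in replicate 2, a mean of 69.1% ± 0.794 (SD, n = 2), and were assigned to no gene. Counts on microRNA genes made up 21.9% ± 0.832 of all reads. In 18 of 20 pairs from the same cluster the multi-copy gene was the lower one (two-sided exact sign test, p = 0.000402), with a median log2 ratio of -6.09. Some pairs share a partner and are not independent; with each partner used once, an alternative added after the data were examined, the multi-copy gene was lower in 14 of 16 pairs (exact sign test, p = 0.00418). Mirlet7a-1 had 184 CPM beside 16851 CPM for Mirlet7d, 2065 bases away, and Mir24-1 had 31.6 CPM beside 6939 CPM for Mir27b. Mir30c-1 had 84.1 CPM and Mir30e 14593 CPM. The exceptions were Mirlet7f-2, at 4586 CPM beside Mir98 at 2746 CPM, and Mir194-2, at 33.7 CPM beside Mir192 at 32.8 CPM. The hairpin of Mir29c, a partner in 1 pair, also shared a stretch of 22 bases with another gene. The 64 listed multi-copy genes held 1.33% ± 0.0303 of the counts, and their levels are uncertain. The median of the 49 detected in at least 1 library was 33.7 CPM, at percentile 6.28 of random lists of detected genes, within their middle 95%. Members such as Mir128-1, at 1481 CPM, and Mir196a-2, at 1128 CPM, were well above it.

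**Figure D4:**
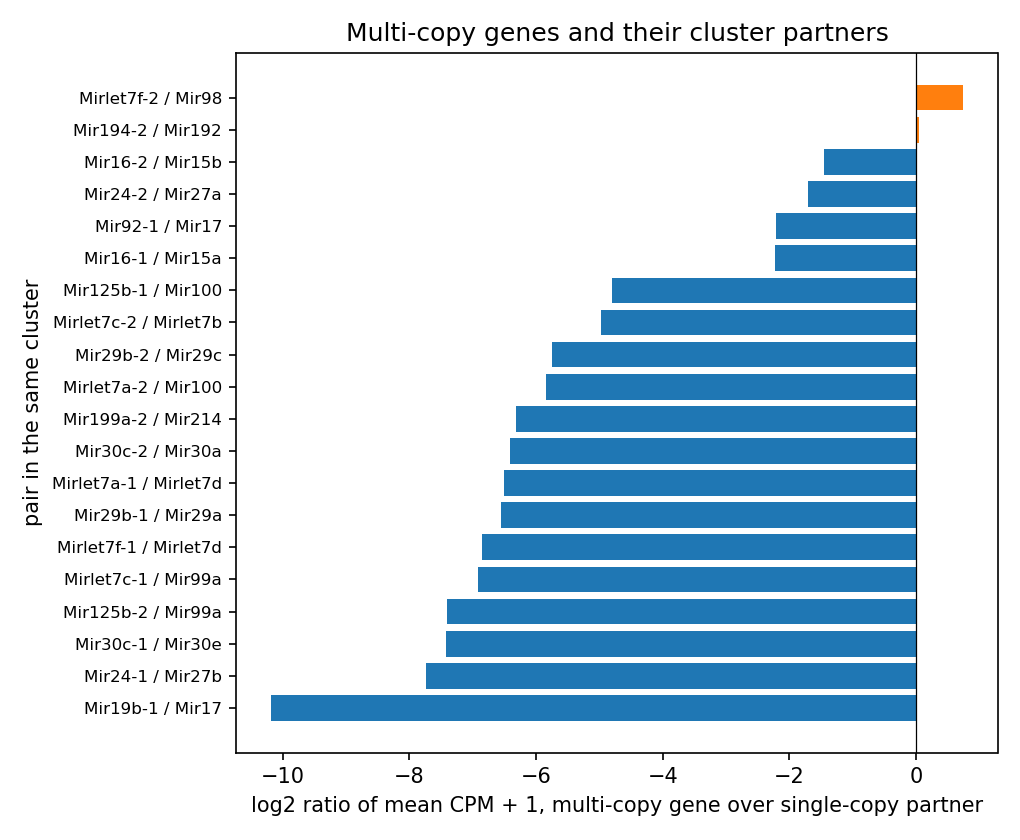
Log2 ratio of mean CPM + 1 of a multi-copy microRNA gene over a partner in the same cluster, for 20 pairs. Bars left of 0 mean that the multi-copy gene was lower, as in 18 pairs.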

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

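The tests of muscle share, of the GC trend on other genes and of slow-fibre genes were chosen after the result was seen; the removal of a GC trend was set before its result, and the test of multi-copy genes before the data were examined. Reads tallied as aligned to several places, which no gene count uses, made up 68.6% of all reads in replicate 1 and 69.7% in replicate 2. The tally does not show which of these reads came from microRNA genes. Reads on the opposite strand of microRNA genes that overlap no other were also seen, 58 in replicate 1 and 79 in replicate 2. Of these, 43 and 25 lay opposite Mir203.

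The low counts of multi-copy genes have the form expected if reads that align equally to several loci were left out. The median log2 ratio over the pairs was -6.09, with 18 of 20 multi-copy genes lower, beyond the bounds set beforehand for that cause. A candidate explanation for the small muscle share is therefore the loss of reads of Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2, which was not tested on reads. No biological explanation was tested.

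Most tested genes of the erythroid, epithelial and smooth muscle and fibroblast lists, and 4 of 8 tested neural genes, were higher in replicate 1. These 4 lists, with 19 detected genes, were picked because they moved, and Mir214 among them was higher in replicate 2. If a lower share of muscle raised markers of all other types alike, their lists would move together. Instead, 6 such lists moved apart by more than the spread of their 26 members (permutation test, p = 0.0051). Genes of the same cluster are not independent in this test, which was chosen after the lists were seen to differ. It speaks only to an equal rise of all types, and a muscle share that changed them unequally stays open. Removing a trend on hairpin GC content left the pooled median at -1.06, from -1.08, but the correction moved other genes as little and decides nothing by itself. A straight-line GC trend estimated on the other detected genes predicted a mean difference of -0.0031 for the 19 genes, against -1.0 observed. The bootstrap 95% interval of the prediction over genes was -0.0081 to 0.0019. Such a small prediction followed from the weak relation of ratio and hairpin GC over the 324 detected genes (rho -0.0172). This argues only against a straight-line trend on hairpin GC shared by the other genes, and GC of the sequenced bases was not measured. Different amounts of other tissue in the samples may account for the pattern, as may differences between their sources, and neither was tested.

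Slow-fibre genes were higher in replicate 2, where a larger share of muscle of any fibre type would raise other muscle genes too. Mir208b and Mir499 had a median log2 ratio of 1.66 and the other 9 detected muscle genes 0.14 (two-sided exact permutation test, p = 0.0364). This test was chosen when the ratios of Mir208b and Mir499 were known. It decides nothing, since 5 of the 11 genes had at least 100 counts in both libraries. These are too few for a p under 0.05 from 10 arrangements. Among these 5, Mir206, at 1.06, lay close to Mir499, at 1.14. Mir486 had 651 CPM in replicate 1 and 717 CPM in replicate 2, and Mir1a-2 was higher in replicate 1, at 378 against 318 CPM. A larger share of muscle in the sample of replicate 2 goes with Mir206 but not with Mir1a-2. However, Mir1a-2 is a multi-copy gene with an uncertain level, and levels of Mir206 by fibre type were not measured. A larger share of muscle and a larger share of slow fibres in that sample thus both remain possible. The labels name no such difference.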

How the results depend on the processing

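Removing Mir206 from the muscle list, thinning replicate 2, placing list levels under other settings, using each partner of the pairs once, list shifts with DESeq2 scaling or relative to the median, and alternatives for single genes were chosen after seeing the data. With all aligned reads as the denominator, the share of the 10 most abundant genes was 14.7% and that of the muscle list 1.32%, since the denominator then includes reads aligned to several places. Without Mir206 the muscle share was 0.204%, by construction. Spearman's rho was 0.903 over the 664 genes with a count in either library, which add genes under a CPM of 2 in at least 1 library. Pearson's r over the same 664 genes was 0.989. The cause of the lower rho was not tested. Leaving out each replicate gave 61.8% to 62.7% for the 10 most abundant genes and 3.64% to 7.50% for the muscle list. Detected genes ranged from 252 to 470 over their alternatives, with 316 after thinning replicate 2 to the total of replicate 1. Genes differing between the libraries ranged from 148 to 172, the coefficient of variation from 22.9% to 25.6%, and the median of the pairs from -5.69 to -6.14. The percentile of the muscle list level ranged from 13.3 to 33.7. In each of 4 alternatives, 6 lists lay outside the random range. TMM scaling, DESeq2 scaling and ratios relative to the median move all genes nearly alike, so they could hardly change these percentiles. Only the pseudocount of 10 CPM could. The limit set by depth is the floor of 1.91 CPM in replicate 1. Mir451a, which lies opposite Mir451b, had an either-strand count of 0 in both libraries and was not tested in that column. The same count was listed for Mir338, opposite Mir3065, and for Mir142, opposite Mir142b. Levels of these genes rest on the strand-specific counts.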

Other observations

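Further lists were measured in the same way. The liver, gut and pancreas list held 0.0156% ± 0.00304 (SD, n = 2) of the counts; Mir122, a microRNA of hepatocytes, had 96.6 CPM in replicate 1 and 50.3 CPM in replicate 2 and was the single gene of 6 tested that differed. The adipose list held 0.0157% ± 0.00196, led by Mir193b at 154 ± 17.6 CPM, and none of its 3 genes differed. The H19-Igf2 locus held 0.106% ± 0.0262, and Mir483, within the Igf2 locus, had 834 and 1208 CPM, higher in replicate 2. The X-linked Mir322-Mir503 cluster held 1.93% ± 0.311, with 3 of 7 genes higher in replicate 1, among them Mir322 at 19078 and 14852 CPM. In the miR-29 family, Mir29a had 1920 and 1169 CPM, and 3 of 4 genes were higher in replicate 1. All 4 passed adjusted over the list alone, with Mir29b-1 higher in replicate 2, at 11.4 and 19.3 CPM.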
